A study of Mus musculus with 2 samples.

How the data were processed

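Peritoneal cells of 2 pools of 4 replicates, Cd36-/- (LysM-Cre and floxed Cd36) and fl/fl (floxed Cd36), were sequenced as 1 library each with the 10x Genomics 3′ v2 protocol, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode, made with software version 3.0.0 per the file headers. Cell Ranger and the mm10 build are named in the submitters' processing notes, which give no annotation release. The matrices hold 31053 genes, with symbols taken from the files. Of the gene IDs, 31011 are in GENCODE M21, an annotation of the same build, which was used only for positions and sequence. All values in the deposited matrices were whole counts, and each barcode had at least 500 UMIs.

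Barcodes with under 200 genes (36 in the Cd36-/- and 38 in the fl/fl library) or over 10% mitochondrial UMIs (509 and 773) were left out, which left 16000 and 14733 cells. Scrublet, run per library in scanpy 1.11.5, marked 1034 (6.46%) and 768 (5.21%) of them as doublets, and these were removed. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were taken for 40 principal components. Cd36, Lyz2, sex-linked, mitochondrial, ribosomal protein, immunoglobulin and T cell receptor variable genes were kept out of this step. Both libraries were clustered together, without alignment between them, by Leiden clustering (leidenalg 0.10.2) at resolution 1 on a graph of 20 neighbours, which gave 23 clusters. Xist gave 1 and 2 UMIs in the whole libraries and the Y-linked Ddx3y 4628 and 4865, so both pools held male cells, and the labels do not state the sex.

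The deposited files hold no cell type annotation. Clusters were therefore named here from lists of markers for 19 cell types and 5 sub-types that were fixed before the data were examined, as were the gene lists, the measures and the rule for named genes. A cluster stayed unnamed if under 3 of a type's markers were detected or its leading genes went against the name, and each name means "like". Large peritoneal macrophages were the clusters with Gata6 and its companion markers, MHC class II macrophages the Retnla cluster, and Gata6-low macrophages the macrophage clusters that remained, which is a description and not a type fixed in advance. 1 unnamed cluster had few UMIs with pancreatic and red cell transcripts, and the other held T and B cell genes together. The fibroblast cluster also held mesothelial markers.

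With 1 library per group there is no spread between replicates, so no test was run and no p-value or standard error is given. Counts were summed per library and class and divided by the class total (CPM, UMIs scaled to the same total per class and library). CPM have exact Poisson intervals, ratios exact conditional binomial intervals, and shares exact Clopper-Pearson intervals at 95%, from which intervals of differences were combined. They cover counting error only. Genes were compared where they had at least 20 CPM in 1 library, and a 2-fold limit describes size only. A share of 0 of n allows up to 3 counts in n. For the 32 gene lists, the median log2 ratio was placed among 10000 random lists of the same size drawn within 20 bins of mean expression. Lists with under 3 members compared got no value.

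The text names Cd36 and Lyz2 first. It then draws on the 15 highest and 15 lowest genes in macrophages and the 5 highest and 5 lowest in other classes with at least 200 cells in each library, ranked by the interval bound nearest to 0. Mitochondrial, ribosomal, immunoglobulin, T cell receptor variable, haemoglobin and sex-linked genes, unnamed gene models and genes under 1/5 of their level in another class in both libraries were left out of that ranking. Up to 4 members per list come from the same ranking. Some genes that the rule names are not reported here. Igkc, C1qa, Trbc2, Timd4 and Gata6 as markers of other cells, and the values of Lyz1 by class, were chosen after the data had been seen.

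The ratio, interval and list steps were tested on simulated counts with the means and depths of 2 classes. For macrophages (4481 genes), 100% of genes with a 3-fold change were called at least 2-fold, 0% of those with 1.5-fold, and 95.1% of intervals of unchanged genes held the truth. For NK cells (5127 genes), 99.0% of genes with a 3-fold change were called at least 2-fold, as were 1.28% of unchanged genes, because counts are lower there. Of 100 simulated lists with no change, 6 lay outside the central 95% for macrophages and 4 for NK cells. The simulated counts varied by counting error alone, each gene on its own, and these lists were random genes. They therefore check the calculation only. They do not give the error rate for real lists, whose genes can vary together, or for differences between animals.

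Alternatives were other filters (at least 500 genes, mitochondrial limits of 5% and 20%, doublets kept), other clusterings (resolution 2, each gene centred within its library, genes with a 2-fold difference left out), and other scalings (median of ratios, TMM from edgeR 4.0.16, each cell given the same total). Further ones were cells thinned to 1818 UMIs with shallower cells left out (1497 and 1137), subtraction of free RNA, and other limits on CPM and fold. Free RNA was estimated per class and library from genes of other cell classes, at 11.4% and 10.8% of UMIs in macrophages and 10.8% and 8.42% in T cells, and most in MHC class II macrophages (25.1% and 22.3%). Genes shared by sequence were found from 31-base words in the last 400 bases of each gene's transcripts. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and igraph 0.11.9.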

Results

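Total peritoneal cells were profiled by single-cell RNA sequencing 3 days after 1 mg of zymosan per animal was injected into the peritoneal cavity of mice aged 10 to 14 weeks. Zymosan is a yeast cell wall preparation that causes a sterile peritonitis, and by this day the inflammation is resolving, per the series title. One library, Cd36-/-, came from mice with floxed Cd36 and LysM-Cre, which acts in macrophages and other myeloid cells. The other, fl/fl, came from mice with floxed Cd36 that carry no LysM-Cre in their strain label. Each library was a pool of 4 replicates, so there was 1 library per group, and no difference given here has a replicate check or a test. The Cd36-/- library held 16543 barcodes with 116600736 UMIs, and the fl/fl library 15537 barcodes with 117238064 UMIs. After filtering and removal of doublets, 14966 and 13965 cells were used, with median depths of 6561.5 and 6892 UMIs per cell. Intervals are exact 95% intervals that cover counting error only, not the spread between animals, and log2 ratios are Cd36-/- over fl/fl. Cells were clustered here, and each cell class name was rebuilt here from fixed markers, so "B cell" stands for B cell-like, and so on.

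The first comparison asked which cells filled the cavity when macrophages carried the Cd36 deletion. Macrophages and monocytes made up 63.3% of cells in the Cd36-/- library (62.5 to 64.1) and 54.3% in the fl/fl library (53.5 to 55.2), 8.97 percentage points more (7.84 to 10.1). B cells made up the difference: their share was 19.7% against 30.4%, a difference of -10.7 points (-11.7 to -9.74). Natural killer (NK) cells were more frequent in the Cd36-/- library, at 3.49% against 2.53%, and T cells were close, at 4.99% and 4.65%. Type 2 conventional dendritic cells (cDC2), which present antigen to helper T cells, were less frequent, at 2.05% against 2.98%. Neutrophils, the cells that flood the cavity early in zymosan peritonitis and are then cleared, were rare in both libraries: 109 cells (0.728%) and 134 cells (0.960%), a difference of -0.231 points (-0.45 to -0.0158).

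B-1 cells, the innate-like B cells typical of body cavities, and follicular B-2 cells were lower together. B-1 cells made up 50.6% of the B cells in the Cd36-/- library and 49.8% in the fl/fl library. Among all cells that were not macrophages, B cells made up 53.6% against 66.6%, T cells 13.6% against 10.2% and NK cells 9.53% against 5.55%, so the lower B cell share was not only a result of more macrophages. Shares sum to 100%, and without cell numbers per cavity it is open whether macrophages were more numerous or B cells fewer. Every barcode in the files had at least 500 UMIs, and neutrophils, with median depths of 730 and 907.5 UMIs, lay close to that limit, so their shares are those of the deeper neutrophils. With at least 500 genes per cell the shares were 0.211% and 0.482%. The neutrophil cluster also held some basophil transcripts. Another 5.23% and 3.57% of cells fell into 2 clusters that were left unnamed.

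Within the macrophages, the balance between resident-type and other macrophages was close. Large peritoneal macrophages (LPM), the resident type that depends on the transcription factor Gata6, made up 39.0% of the class in the Cd36-/- library and 39.6% in the fl/fl library, a difference of -0.532 points (-2.02 to 0.95). Macrophages with low Gata6, which held clusters led by Folr2, by Chil3 and by cell cycle genes, made up 57.9% and 55.2%. The Chil3 cluster was larger in the Cd36-/- library, at 14.1% of macrophages against 11.4%. Macrophages rich in MHC class II genes and Retnla were fewer, at 3.05% against 5.26%. Clusters of cycling cells made up 17.6% and 17.1% of macrophages. Gata6 itself was alike inside the LPM sub-class (log2 ratio -0.02), but Timd4, another of its markers, was higher (0.38), so this split rests on genes that were not all alike.

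**Figure D1:**
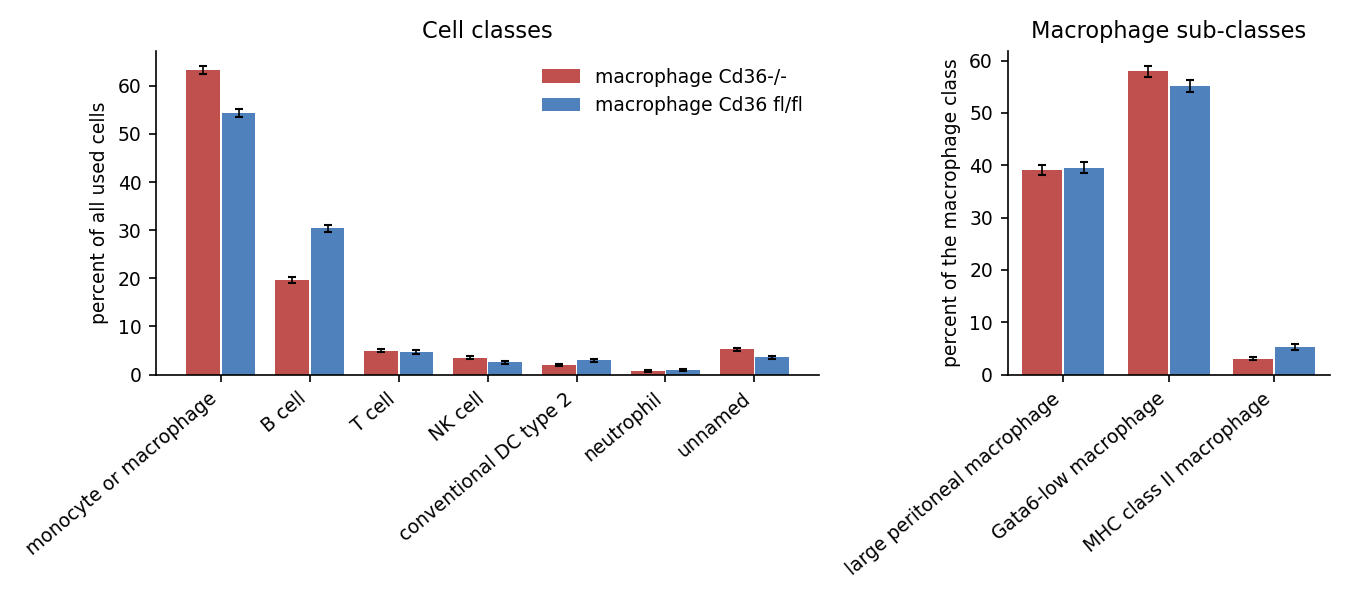
Share of each cell class among all used cells (left, percent) and of each sub-class among macrophages (right, percent) in the Cd36-/- and fl/fl libraries, with exact 95% counting intervals. Macrophages and monocytes took 63.3% against 54.3%, B cells 19.7% against 30.4%, and the LPM share of macrophages was 39.0% against 39.6%.

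The second comparison was of Cd36, the scavenger receptor for oxidised lipoproteins and long-chain fatty acids that the deletion targets. In macrophages Cd36 stood at 172 CPM (UMIs scaled to the total of the class) in the Cd36-/- library (169 to 175) and 242 in the fl/fl library (238.3 to 245.5), a log2 ratio of -0.49 (-0.53 to -0.46). It was lower in LPM (182 against 277 CPM), in Gata6-low macrophages (168 against 222 CPM) and in MHC class II macrophages (134.0 against 254.9 CPM). B cells, in which LysM-Cre is not expected to act, had 32.7 and 31.3 CPM. T cells had 13.2 and 14.2 CPM and NK cells 13.4 and 13.5 CPM, levels that free RNA from macrophages can give. In cDC2 Cd36 was as low, at 12.7 and 13.9 CPM (log2 ratio -0.13, -0.81 to 0.52). At least 1 Cd36 UMI was seen in 65.9% of Cd36-/- macrophages and 75.4% of fl/fl macrophages, at median depths of 8199 and 9162 UMIs. After thinning of every cell to 1818 UMIs these shares were 25.7% and 34.1%. In T cells, which should lack the gene, they were 3.88% and 5.08% at median depths of 2633 and 3267 UMIs, and 1.82% and 3.09% after thinning. The labels do not say which part of Cd36 was floxed. UMIs from the 3′ end can still be made when an inner exon is deleted, so a level 29.0% lower does not measure how completely Cd36 was deleted. Of the Cd36 values, only the direction serves as a check of the labels. Cd36 (ENSMUSG00000002944) lies on chromosome 5 at 17781690 to 17888801 in mm10.

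Lyz2, the lysozyme gene that hosts the Cre in LysM-Cre mice, was lower in macrophages of the Cd36-/- library, at 17979 against 29086 CPM (log2 ratio -0.69). It was lower in each of the 9 macrophage clusters. Its neighbour and near copy Lyz1 was higher, at 2674 against 553 CPM, and in the LPM cluster led by Alox15 it was 12.8-fold higher. Lyz2 and Lyz1 lie next to each other on chromosome 10, with 37.0% and 38.4% of their 3′ sequence words shared with other genes, so the split of UMIs between them is uncertain. If the fl/fl mice carried no Cre, as their strain label reads, the loss of Cd36 and the presence of Cre in Lyz2 cannot be told apart in any gene described here.

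**Figure D2:**
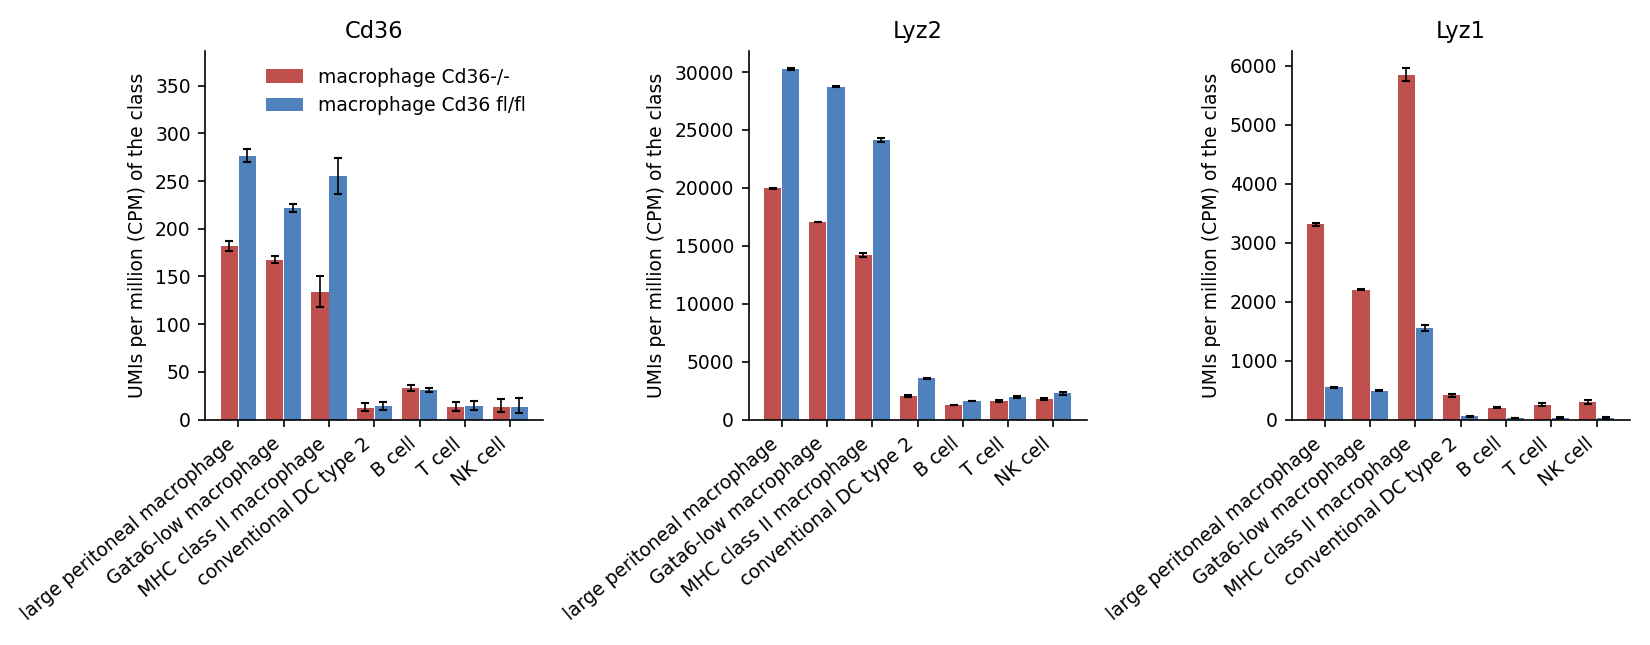
CPM of Cd36, Lyz2 and Lyz1 in 7 cell classes of the Cd36-/- and fl/fl libraries, with exact 95% Poisson intervals. In LPM, Cd36 stood at 182 against 277 CPM and Lyz1 at 3310 against 550 CPM.

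The third comparison asked how macrophage transcripts differed between the libraries. Most did not: of 4594 genes with at least 20 CPM in 1 library, 99.3% lay within 1.5-fold. By size alone, 1 gene was at least 2-fold higher in the Cd36-/- macrophages (Lyz1) and 5 were at least 2-fold lower. Those 5 were Per1 (7.13 against 29.4 CPM, log2 ratio -2.04), Fkbp5 (-1.47), Lepr (-1.13), AY036118 (-1.11) and Klf9 (49.6 against 99.5 CPM). Per1, Fkbp5 and Klf9 are induced by glucocorticoids, and so is Tsc22d3, an anti-inflammatory mediator of these hormones, which was also lower (159 against 261 CPM, -0.71). They were picked out because they were among the lowest, and a list of 20 other glucocorticoid-induced genes was made only after these had been seen. Of that list, 10 genes reached 20 CPM in macrophages, with a median of 0.02 and 5 higher, and over all 20 genes 6 were higher and 14 lower, with Cxcr4 at 4.11 against 13.3 CPM and Ddit4 with a log2 ratio of -1.71. Lepr is the leptin receptor, and Thbd, which encodes thrombomodulin, was lower too (11.2 against 21.9 CPM, -0.97).

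Among the genes that were higher, Apoe stood out. The apolipoprotein that carries cholesterol out of macrophages was at 3202 against 1824 CPM, 1.75-fold higher (log2 ratio 0.81). The transcription factor Irf1 (0.78) and the GTPases Igtp (0.78) and Gbp2 (0.58) were higher as well. The growth factor Igf1 was at 30.3 against 20.5 CPM (0.56). Fcgr2b, the inhibitory receptor for IgG (-0.62), the transglutaminase F13a1 (-0.57), the chaperone Hsph1 (-0.89) and Axl, a receptor that takes up dying cells (-0.60), were lower. Further genes named by the rule were Sgms1 (-0.73), Pik3r5 (-0.58) and Rnf169 (-0.60) on the lower side, and Grcc10 (0.61), Erh (0.52), Hist1h2ap (0.50) and Cox16 (0.54) on the higher side. Tpm3-rs7 (0.92), Gstp1 (0.74) and Bloc1s1 (0.53) were higher in macrophages, but they were higher in every compared class, and they share much 3′ sequence with other genes, so they are uncertain. AY036118 was lower in every compared class, and 100% of its 3′ sequence words are shared with other genes, so it is uncertain too.

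**Figure D3:**
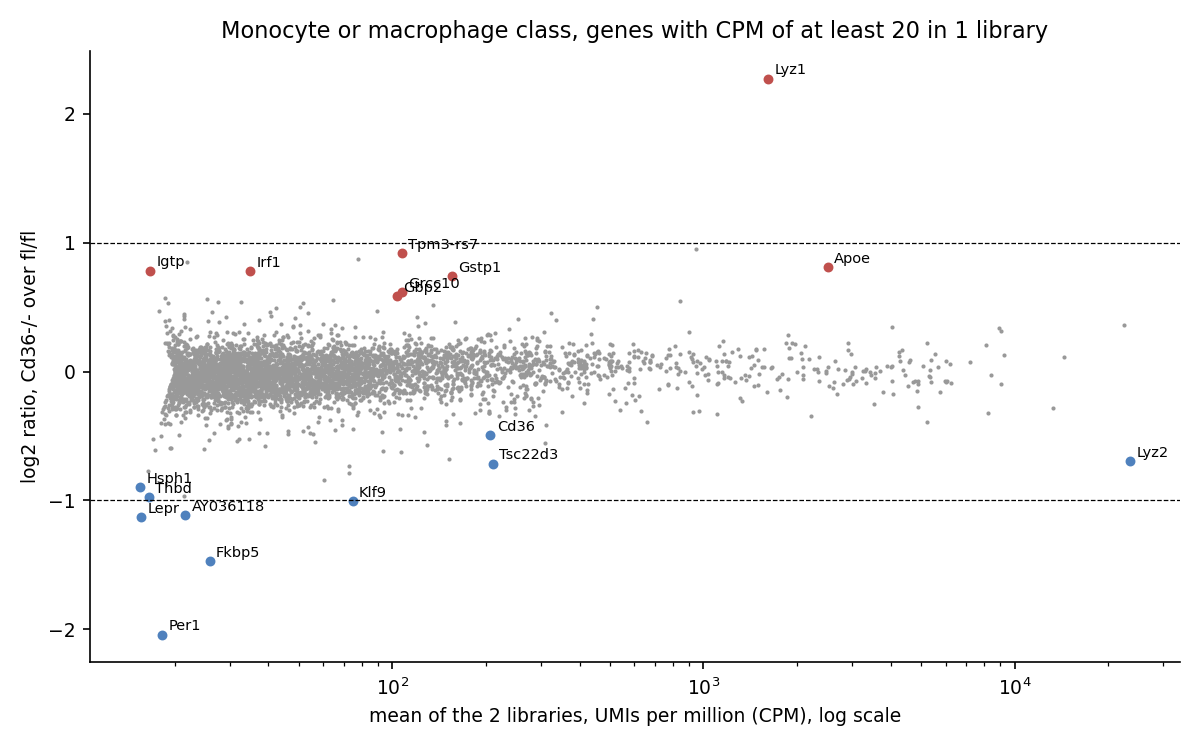
Log2 ratio of each gene in macrophages (Cd36-/- over fl/fl) against its mean CPM in the 2 libraries on a log axis, for 4594 genes, with dashed lines at 2-fold. Lyz1 lies above the upper line at 2.27 and Per1 below the lower line at -2.04, and Lyz2, at the right edge, has a log2 ratio of -0.69.

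Gene lists fixed before the data were examined placed these genes in pathways. The median log2 ratio of each list was set against 10000 random lists of the same size and expression, as a description of these 2 libraries. In macrophages, 9 lists lay outside the central 95% of random lists, and their medians were small. Cholesterol efflux and LXR target genes were higher (median 0.13, 7 of 9 members), led by Apoe and with Apoc1 (0.27) and Mylip (0.25). Chemokines were higher (median 0.27, 6 of 8), with Cxcl2 (49.5 against 35.2 CPM), Pf4 (2045 against 1684 CPM) and Cxcl13 (478 against 391 CPM). Type I interferon response genes were higher (median 0.10, 6 of 8), with Rtp4 (0.43) and Zbp1 (0.36), while Ifi27l2a was lower (-0.24). Scavenger receptors went apart: Marco was higher (0.46) and Mrc1 (-0.35) and Stab1 (-0.32) lower, with a median of 0.14. The scavenger receptor list came back inside the central 95% when members from 5 CPM were taken, and the interferon list when free RNA was subtracted.

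Genes of the respiratory chain went in opposite directions by genome. Of the 42 nuclear oxidative phosphorylation genes, 35 were higher (median 0.09), with Sdhb at 224 against 183 CPM. All 12 mitochondrially encoded genes were lower (median -0.14), with mt-Nd3 at 250 against 367 CPM. The mitochondrial share of UMIs, which is also a measure of cell quality, differed between the libraries before filtering (medians of 2.695% and 2.958% per barcode, with 509 and 773 barcodes over the 10% limit). Unfolded protein response genes were lower (median -0.13, 11 of 15), with the chaperones Hspa5 (-0.24) and Hsp90b1 (-0.23) and with Herpud1 (-0.45). Cell cycle genes had a median of -0.09, with 14 of 22 lower. The LPM identity list had a median of 0.10, but it left the central 95% only by a small margin and came back inside it under each of the 3 alternative settings tried.

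The lists closest to what Cd36 does, fatty acid handling, lay within the central 95% in macrophages as a whole. PPAR target genes had a median of -0.08 (5 of 8 lower), with the lipid droplet protein Plin2 at 246 against 303 CPM and Fabp4 at 352 against 402 CPM. Fatty acid uptake and transport genes had a median of 0.01, fatty acid oxidation genes of -0.03 (Cpt1a, -0.21) and lipid droplet genes of -0.09. Fatty acid synthesis genes had a median of -0.12 over 3 members and cholesterol synthesis genes of 0.02 over 3. Apoptotic cell uptake genes had a median of -0.06, with Mertk (-0.43) and Axl lower and Timd4 (0.40) higher. Thbs1, a CD36 ligand that also bridges dying cells to macrophages, was at 482 against 594 CPM (-0.30). Pro-resolving factors (median 0.05), alternative activation genes (-0.11), inflammatory cytokine and NF-kappaB target genes (0.10) and complement genes (0.10) also lay inside, as did MHC class II (0.07), NADPH oxidase (-0.02), antioxidant (0.05), iron (0.08), lysosome (0.02) and glycolysis genes (-0.02). So did the handling list of immediate early and heat shock genes (-0.03), matrix genes (-0.05), neutrophil ageing (-0.02) and granule genes (-0.03) and B cell activation genes (-0.01).

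The macrophage sub-classes differed in where these lists stood. In LPM, cell cycle genes were lower (median -0.35, 18 of 19), with Ccnb2 at 19.8 against 37.6 CPM and Mki67 at 21.3 against 34.6 CPM. The cycling cluster made up 10.4% of LPM against 11.3%, a difference of -0.942 points (-2.47 to 0.573). Its cells had median depths of 10548.5 against 13631.5 UMIs, so each tended to add fewer UMIs to the summed counts of the Cd36-/- library. The list median is therefore not a measure of fewer cycling cells. The share of LPM with a Mki67 or Top2a UMI was 12.2% (11.16 to 13.29) against 14.1% (12.83 to 15.35). After thinning it was 5.69% (4.95 to 6.50) against 6.89% (5.99 to 7.88). The intervals overlap in both cases. Higher in LPM were type I interferon response genes (median 0.29, 6 of 7), all 10 complement genes (median 0.17, C1qa 2641 against 2087 CPM), all 8 chemokines (median 0.20) and cholesterol efflux genes (median 0.23, Abca1 0.24). Retnla was at 127 against 52.2 CPM in LPM, but the alternative activation list that holds it lay inside the central 95% there (median -0.0698, 2 of 4 members higher).

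In Gata6-low macrophages 3 of the lowest genes of the whole class were further apart: Fkbp5 was at 7.31 against 37.3 CPM (log2 ratio -2.35), Per1 at -2.22 and Klf9 at -1.35. Apoe was at 3263 against 1671 CPM (0.97) and the GTPase Gbp2b at 29.0 against 13.2 CPM (1.13), while the type I interferon list lay inside the central 95% (median 0.029). Inflammatory and NF-kappaB target genes were higher (median 0.28, 4 of 6), with the acute phase protein Saa3 at 12370 against 8068 CPM, though Nfkbia was lower (-0.35). LPM markers were higher in these cells too (LPM identity list, median 0.21, 8 of 11, Timd4 at 160 against 118 CPM), and Saa3 is itself among the leading genes of an LPM cluster. Alternative activation genes were lower (median -0.24, 6 of 7), with Retnla at 132 against 170 CPM and Mrc1 (-0.33), and so were unfolded protein response genes (median -0.21, 12 of 14). In the small MHC class II sub-class, with 289 and 399 cells, alternative activation genes were instead higher (median 0.39, 6 of 8), with Ccl24 at 166 against 60.2 CPM and Arg1 at 40.4 against 23.9 CPM. LPM markers were higher beside them (median 0.46, 6 of 8, Timd4 at 88.2 against 51.3 CPM), though their median was -0.25 with free RNA subtracted, and Ccl24 is among the leading genes of an LPM cluster. PPAR target genes were lower there (median -0.29, 5 of 8), with Lpl (-0.32) and Klf4 (-0.40). Retnla, which was at 7148 against 4465 CPM, is 1 of the markers of that sub-class and is not read as a result. Its levels in LPM and Gata6-low macrophages were far lower, and RNA or cells of the MHC class II sub-class may add to them.

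**Figure D4:**
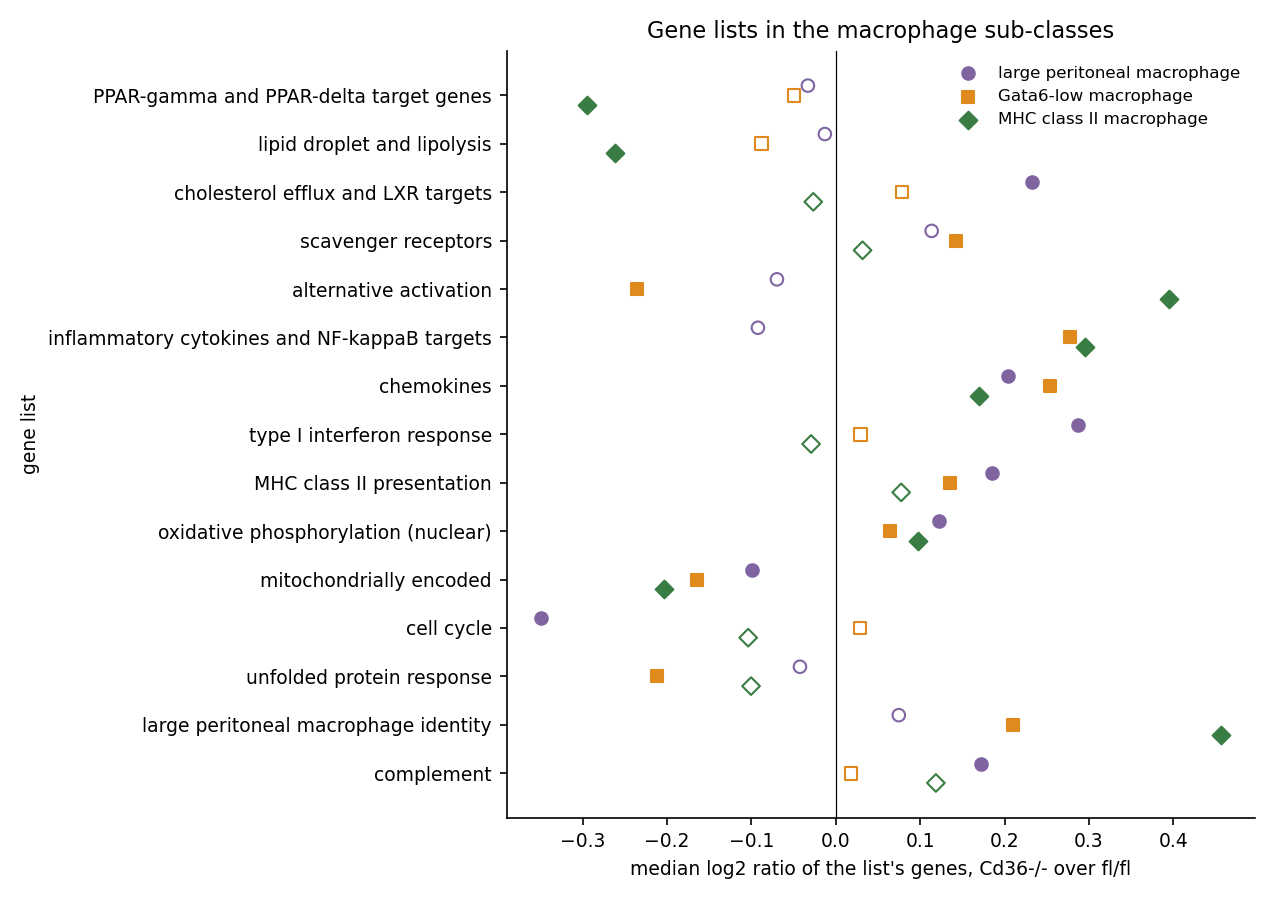
Median log2 ratio (Cd36-/- over fl/fl) of gene lists in the 3 macrophage sub-classes, for lists outside the central 95% of random lists in at least 1 of them. Filled symbols lie outside the central 95% and open symbols inside. Cell cycle genes lie lowest in LPM at -0.35, and alternative activation genes lie at -0.24 in Gata6-low and 0.39 in MHC class II macrophages.

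The fourth comparison took the lymphocytes, in which LysM-Cre is not expected to act, and cDC2, which are myeloid cells that it can reach. Cd36 in cDC2 was as low as in T and NK cells in both libraries, so no loss of it could be seen there. NK cells, with 523 and 354 cells, showed the furthest separation: the cytotoxic protease Gzmc was at 229 against 3.12 CPM, from 3 UMIs in the fl/fl library, a log2 ratio of 6.20 (4.63 to 8.48). Of 27 cell cycle genes, 13 reached 20 CPM in 1 library of NK cells, and all 13 were higher (median 0.85), with Pclaf at 40.9 against 4.16 CPM, Stmn1 at 160 against 48.9 CPM and Top2a at 42.4 against 11.4 CPM. Pclaf and Top2a reached 20 CPM only in the Cd36-/- library, and members under the limit were not counted. The count of 13 can therefore partly reflect the limit. At least 1 Mki67 or Top2a UMI was found in 27 NK cells (5.16%, 3.43 to 7.42) against 14 (3.95%, 2.18 to 6.55), and after thinning in 17 (4.42%, 2.59 to 6.98) against 6 (1.93%, 0.711 to 4.15), with intervals that overlap. Heat shock and immediate early genes were lower in NK cells (median -0.22, 7 of 10), with Hsph1 at 17.3 against 38.5 CPM, a list that came back inside the central 95% when members from 5 CPM were taken.

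In B cells all 13 unfolded protein response genes were lower (median -0.11), with Hspa5 at -0.36, and the chaperones Hsph1 (15.6 against 42.0 CPM, log2 ratio -1.43) and Dnaja1 (-0.96) were lower too. Ccnd2, a cyclin of B cell growth, was at 154 against 306 CPM and the stress gene Ddit4 at 27.3 against 53.2 CPM. MHC class II genes were slightly higher (median 0.18, 10 of 11), with H2-Oa at 0.43. In T cells 5 of 5 cholesterol synthesis genes were higher (median 0.63), and T cell activation genes were higher (median 0.35, 6 of 7), with Icos (0.38) and Cd69 (0.38). Hsph1 was lower again (-1.52). In cDC2 the chemokine Ccl17 was at 8.71 against 55.0 CPM (-2.66), and 11 of 11 cholesterol synthesis genes were higher (median 0.39), with Insig1 at 0.75. MHC class II genes were a little lower in cDC2 (median -0.08, 8 of 10).

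Free RNA limits the comparison of these smaller classes. Macrophage transcripts such as C1qa (132 against 91.4 CPM in B cells) were higher in the lymphocytes of the library with more macrophages, so lists made up mostly of macrophage genes were not read there. Igkc, a B cell transcript, was at 267 against 356 CPM in macrophages. The estimated free RNA was highest in MHC class II macrophages, at 25.1% and 22.3% of UMIs. Pancreatic transcripts, foreign to all these cells, were among the lowest genes of T cells (Ins1 at 0.456 against 24.5 CPM) and NK cells (Gcg at 0.786 against 26.0 CPM, Ins1 at 50.3 against 109 CPM). The cDC2 class also held lymphocyte transcripts, more so in the Cd36-/- library (Trbc2 at 110 against 59.7 CPM, and Igkc at 2415 against 1797 CPM), so its values may mix in other cells.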

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

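In several gene lists the median log2 ratio lay above the central 95% of random lists in 1 cell class and below it in another, and these differences between classes were not tested. For alternative activation genes, the median in MHC class II macrophages was 0.63 above that in Gata6-low macrophages and 0.79 above that in T cells, where only 3 members could be compared: Il4ra and Socs1, which were lower, and Retnla, at a level that free RNA can give. Retnla, which defines the MHC class II sub-class, is a member of that list.

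Cell cycle genes in LPM lay below those in 3 other classes: NK cells stood 1.199 above LPM, cDC2 0.61 and B cells 0.52. For MHC class II presentation genes, Gata6-low macrophages stood 0.22 and B cells 0.26 above cDC2, a class that also held lymphocyte transcripts.

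Insulin RNA was found in T cells, NK cells and macrophages and also in data that no comparison used: in the unnamed cluster of few UMIs, Ins2 was at 1766 CPM in the Cd36-/- library and 2459 CPM in the fl/fl library, from 2334 and 1759 UMIs.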

How the results depend on the processing

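Choices named here were made before the data were examined, except leaving out the unnamed clusters or genes shifted alike in every class, and the alternatives for the B cell share and single genes. Each of the 3 other share differences (neutrophils, B cells and LPM among macrophages) stayed within its counting interval under each of its alternatives, but with at least 500 genes the neutrophil shares themselves were 0.211% and 0.482%. The macrophage share difference of 8.97 points was larger with at least 500 genes (10.2), mitochondrial limits of 5% (10.45) and 20% (10.6), and the unnamed clusters left out (10.5). The Cd36 log2 ratio in macrophages of -0.49 became -0.45 with median-of-ratios scaling, -0.46 with TMM and -0.54 with equal totals per cell. Of 1243 alternative values for single genes, 1092 lay within the counting interval and none changed sign. Median-of-ratios and TMM scaling moved the log2 ratios of a class by less than 0.1, most in T cells (-0.0877). Depth limits the smaller classes most: in NK cells 1.28% of unchanged simulated genes passed 2-fold, in macrophages 0%. With thinned cells the difference in cell cycle share went from -0.468 to 0.227 points in macrophages, -0.543 to 0.693 in Gata6-low macrophages and -1.86 to -1.20 in LPM, each within its interval.

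The count of 1 gene at least 2-fold higher in macrophages became 2 with equal totals per cell, at least 500 genes, a mitochondrial limit of 5%, doublets kept, 2-fold genes left out of the clustering or genes centred within each library. It became 3 with thinned cells, 6 at 5 CPM or more, 10 at a 1.5-fold limit and 0 without genes shifted alike. Lyz1 was among them in all but the last, and the added genes at 20 CPM and 2-fold were Acod1 and Ins2. The count of 5 genes at least 2-fold lower became 9 at 5 CPM or more, 0 at 100 CPM or more and 21 at 1.5-fold, limits that by construction admit more or fewer genes. It was 4 with median-of-ratios or TMM scaling, thinned cells, a mitochondrial limit of 5% or genes shifted alike left out, 6 with equal totals or free RNA subtracted, and 7 with a mitochondrial limit of 20%. Klf9 was not among them with either of those scalings, equal totals, thinned cells or the 5% limit, and Lepr not with thinned cells.

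Of 221 alternatives for 74 list medians, 192 kept their side of the central 95% (some inside changed sign) and 3 outside reversed. With members from 5 CPM, scavenger receptors in Gata6-low macrophages reversed from 0.14 to -0.0623. With free RNA subtracted, chemokines in Gata6-low macrophages reversed from 0.25 to -0.0848 and the LPM identity list in MHC class II macrophages from 0.46 to -0.25. Others came back inside the central 95%. With members from 5 CPM: scavenger receptors (0.0441) and LPM identity (0.0873) in macrophages, MHC class II (0.0588) and oxidative phosphorylation genes (0.0638) in Gata6-low macrophages, lipid droplet (-0.00097) and inflammatory genes (0.13) in MHC class II macrophages, immediate early and heat shock genes in NK cells (-0.0709), and fatty acid uptake (-0.20), pro-resolving (0.27) and neutrophil ageing genes (-0.0037) in cDC2. With free RNA subtracted: type I interferon (0.0859) and LPM identity (0.0803) in macrophages, mitochondrially encoded genes in LPM (-0.0924), oxidative phosphorylation in Gata6-low macrophages (0.057), lipid droplet (-0.32), inflammatory (0.14) and chemokine genes (0.14) in MHC class II macrophages, cholesterol efflux (0.13) and cell cycle genes (0.11) in B cells, antioxidant genes in T cells (0.0986), and pro-resolving (0.29) and neutrophil ageing genes (-0.0781) in cDC2. With median-of-ratios scaling: LPM identity in macrophages (0.14) and neutrophil ageing genes in cDC2 (-0.14). Members from 5 CPM moved cholesterol synthesis (0.0513) and matrix genes (-0.0928) in macrophages outside it. The cause was not tested. No paired analysis was possible because each group had 1 library.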

Other observations

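Interferon-induced genes were also higher in dendritic cells. In cDC2, 6 of 7 type I interferon response genes were higher in the Cd36-/- library (median log2 ratio 0.29), with Rtp4 (0.75), while Ifi27l2a was lower (-0.31). The GTPase Igtp, which is not in that list and was named for its large ratio, was higher too (1.21). PPAR target genes were lower in cDC2 (median -0.30, 4 of 6), with Plin2 at 66.1 against 83.7 CPM. Wls, a carrier of Wnt proteins, was lower in cDC2 (100.1 against 200.7 CPM) and in B cells (42.5 against 84.2 CPM). In NK cells Spp1, which encodes osteopontin, was at 50.3 against 6.24 CPM and Pik3ip1, a brake on PI3 kinase, at 17.3 against 46.8 CPM.

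The unnamed cluster of few UMIs (620 and 422 cells) differed in its foreign transcripts. The pancreatic hormone gene Ppy was at 482 CPM in the Cd36-/- library and 4.19 CPM in the fl/fl library, and the globin gene Hbb-bs at 2.27 and 3700.5 CPM.

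All tests in the paragraphs below were chosen only after the patterns had been seen, and each prediction was written before its test was run. That the pools differ in genotype, in Cd36 and, per the strain labels, in Cre, stays open as an untested explanation for each pattern.

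Per1, Fkbp5, Klf9 and Tsc22d3, all induced by glucocorticoids, were lower in the Cd36-/- macrophages, and a difference in depth would not leave them lower after thinning (median log2 ratio -1.16 with thinned cells and -1.24 without). These 4 genes also had log2 ratios below 0 in B-1, B-2, T and NK cells. Only Tsc22d3 had an interval below 0 in each of those classes (-0.30, -0.18, -0.21 and -0.45), and Per1 and Klf9 stayed under 20 CPM there. For a stress hormone that reached all cells, a list of other glucocorticoid-induced genes was to lie below the central 95% of random lists in macrophages too, but it did so only in 3 of 4 lymphocyte classes (B-1, B-2 and T cells), with a median of 0.02 at percentile 59.6 in macrophages. Over all 20 genes of the list, 14 were lower in macrophages, 10 in B-1 cells, 7 in B-2 cells, 11 in T cells and 12 in NK cells. Within the list, Cxcr4, Txnip and Pik3ip1 had intervals below 0 in macrophages and in each of these lymphocyte classes. Cxcr4 was at -1.70 in macrophages and -1.21, -1.04, -0.85 and -0.81 in B-1, B-2, T and NK cells. Cxcr4 and Pik3ip1 stayed under 20 CPM in macrophages. None of the list had an interval above 0 in all of these classes. Clock output genes over the whole libraries had a median of -0.33, with 6 of 7 lower, short of the -0.5 set in advance for a different time of day at collection, and the genes of the opposite phase were at -0.02. Neither a hormone nor the time of day could be excluded.

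Lyz2 was lower and Lyz1 higher in the Cd36-/- library. Were reads only moved from one copy to the other, the gain would match the loss, but Lyz1 gained 2121 CPM where Lyz2 lost 11107 CPM, a ratio of 0.191. The 20 expressed genes within 5 Mb, with Lyz1 and Lyz2 left out, had a median absolute log2 ratio of 0.0641, at percentile 9.44 of 4175 runs of neighbouring genes. A median over 20 genes does not speak to a haplotype that came with the Cre allele and changes only a few genes, so this stays open. In neutrophils, myeloid cells that LysM-Cre can also reach, Lyz2 was at 7950 against 8205 CPM (log2 ratio -0.046, -0.17 to 0.08). Fibroblasts held about as much Lyz2 (8703 and 9773 CPM), so free RNA may supply much of the value in the shallow neutrophils. Loss of Lyz2 transcripts from the allele that hosts Cre remains a hypothesis that these libraries cannot test.

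A set of 9 genes was shifted alike in every compared class. Among them, Lyz1, Tpm3-rs7, Gstp1, Bloc1s1 and Gm26532 were higher and AY036118, Gm10036 and Gm42418 lower. A candidate explanation is that reads were assigned differently between near-identical copies: the genes shared a median of 51.6% of their 3′ sequence words with other genes, at percentile 100 of random sets (median 0.436%). Gm26532 and Gm42418 shared 0%, so it cannot account for them. Free RNA from macrophages would need genes far lower in lymphocytes, which held for 11.1% of them (Lyz1 alone). What would change read assignment between the libraries was not tested.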
